A study of Homo sapiens with 24 samples.

How the data were processed

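The series holds RNA sequencing of clones of the HT-29 colon adenocarcinoma line that carry a lentiviral vector with a doxycycline-inducible shRNA against ephrinB2. Per the labels, cells were kept without doxycycline or given 1 µg/ml for 24 hours, total RNA was treated with DNase, and stranded total RNA libraries were made. Clone 596-7 was sequenced on NextSeq (4 untreated and 4 treated libraries). Clones 596-1, 596-6, 596-7 and 596-11 were sequenced on NovaSeq (2 untreated and 2 treated libraries of each, 16 in all). Every library was mapped to a group by its title and column name, and 0 columns of the tables had no sample.

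Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, trimmed with cutadapt 1.18, aligned to hg38 with STAR 2.7.6a and quantified with RSEM 1.3.3. The authors then deposited 1 table per platform of log2 CPM after voom and quantile normalization with limma 3.48.3. The NextSeq table lists 14153 features, 14146 human genes and 7 features of the vector. The NovaSeq table lists 14724, of which 14714 are human genes and 10 belong to the vector. Of the human gene identifiers, 14117 and 14684 are in GENCODE 29 (99.8% of each table), 6409 and 6875 of them with the same version number, so coordinates are those of GENCODE 29 on hg38.

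The tables hold no counts and no library totals, so the depth per library is unknown and no model of counts could be fitted. What precision the values have was read from their spread. Within groups, libraries correlated at 0.985 to 0.994 (NextSeq) and 0.968 to 0.995 (NovaSeq), and no pair of libraries was identical. The median standard error of a log2 fold change was 0.0785 for the NextSeq comparison of 4 with 4, 0.142 for a clone's NovaSeq comparison of 2 with 2, and 0.116 for a clone against the other 3 untreated clones. As both tables were normalized separately, values were tested only within a table.

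Features were kept if at least 4 NextSeq or at least 2 NovaSeq libraries had a log2 value of 0 or more, which left 13681 and 14357 features for testing and set aside 472 and 367. Linear models with 1 mean per group were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts, eBayes with a trend). P-values are 2-sided and were adjusted by the Benjamini–Hochberg method within each contrast, and an adjusted p under 0.05 is a call. Vector features were part of the fit and the adjustment, but all counts given are of human genes. The contrasts were doxycycline in NextSeq 596-7, doxycycline in each NovaSeq clone, the mean of those 4 differences, their interaction (F test), the untreated clones against each other (F test), and each untreated clone against the mean of the other 3. All 16 NovaSeq libraries shared 1 estimate of spread. An exact permutation test of the 8 NextSeq values was added for EFNB2.

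A set of 36 gene lists was fixed, and lists with 5 or more measured members were tested with camera (preset correlation 0.01) in each contrast, with Benjamini–Hochberg adjustment over the lists. Each test was repeated with an estimated correlation and with fry. The same test was run with the genes of each chromosome as sets for the untreated clones. Overlaps of calls between clones were compared with the number expected for independent lists and tested with Fisher's exact test.

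Genes to name were set by a rule: EFNB2 throughout, the largest fold changes among calls whose libraries did not overlap or whose direction was shared, the lowest p-values in the interaction, and the lowest p-values within lists and called chromosomes. Loci with clone-based names and pseudogenes were passed over and counted, and results for a few items met by this rule or picked later are not reported here. The groups, contrasts, thresholds, lists, naming rule and alternative settings were fixed before the data were examined. Exceptions, chosen after their values were seen, are the vector features, genes induced in all clones and neighbouring induced genes. The settings and tests said below to be added or chosen later are exceptions as well.

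The pipeline was tested on simulated data with changes added to values of the same spread. In the NextSeq design 26%, 58%, 88% and 98% of genes with a true log2 change of 0.25, 0.5, 1 and 2 were called, and in a NovaSeq clone of 2 with 2 these shares were 4%, 38%, 70% and 88%. Of all calls 7.02% and 6.90% were false, the raised list was called and 0 other lists were. The simulated genes varied independently, so this cannot show how the list test behaves when genes vary together. The simulated values had the same spread, and only 50 genes were changed at each size outside the raised list. In the data most genes were called in the largest response, and the counts of the smaller responses depended on the spread used. The shares of genes called and of false calls therefore hold for the simulated setting only. They were not tested for groups of unequal spread or for a change of most genes.

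Alternative settings were no filter on low values, a stricter filter (mean log2 value of 1 or more), centring each library on its median, renewed quantile normalization, eBayes without a trend and robust, a replicate block, leaving out each library in turn, fits of only the groups compared, the untreated contrasts repeated among treated libraries, and an added requirement of an absolute log2 fold change of 1. Centring on the cytosolic ribosomal protein genes, leaving aside the first untreated libraries of 596-1 and 596-7 together, and leaving aside clone 596-7 were added later. Reads were not in the deposit, so junctions between vector and genome, mutations and allele shares could not be examined.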

Results

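To examine what induction of the vector does in HT-29 clones, RNA was compared with and without doxycycline within 596-7 on NextSeq and within 4 clones on NovaSeq, and between the untreated clones. No library of parental HT-29 cells, of a non-targeting shRNA or of doxycycline alone is among those analysed here, so each response is to the drug, the shRNA and the rest of the vector together. The labels do not say whether replicates are separate cultures, and the p-values measure the spread between libraries.

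Did doxycycline lower the RNA of the targeted gene? EFNB2 (chromosome 13, 106489731 to 106535662, minus strand) encodes ephrinB2, a membrane ligand of Eph receptors. On NovaSeq it fell in 596-1 (mean log2 CPM 6.31 to 5.45, log2 fold change -0.86, SE 0.0773, adjusted p = 0.000129), in 596-6 (6.12 to 5.50, -0.61, adjusted p = 0.00286) and in 596-11 (5.53 to 5.08, -0.45, adjusted p = 0.00678), with both treated libraries below both untreated ones in each. In 596-7 it was higher in the libraries labelled as treated, on NovaSeq (5.45 to 7.22, 1.77, adjusted p = 4.13e-09) and on NextSeq (5.90 to 8.09, 2.19, SE 0.0405, adjusted p = 1.07e-11), again without overlap. The exact permutation p of the NextSeq values was 0.0286, the smallest that 70 splits can give. The effect differed between clones (interaction adjusted p = 2.84e-08). With 596-7 left aside no difference between the other 3 was called (0.665, adjusted over all tested features). This does not show that their changes of -0.86, -0.61 and -0.45 were equal. The mean over the 4 clones was -0.04 (adjusted p = 0.437), and over the 3 others -0.64 (4.72e-06). Leaving out 1 library ended the call in 596-6 (second untreated library out, adjusted p = 0.0538) and in 596-11 (first untreated out 0.0647, second untreated out 0.0726, second treated out 0.0894). After centring on ribosomal protein genes the falls were -0.91, -0.46 and -0.26 with adjusted p of 0.0596, 0.418 and 0.569, and fitted on its own 4 libraries 596-1 had an adjusted p of 0.471.

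Several vector features, looked at after their values were seen, rose in every clone given doxycycline. The reporter RFP rose by 11.77 on the log2 scale in NextSeq 596-7, and on NovaSeq its mean log2 CPM went from 4.15 to 12.12 in 596-1, 3.17 to 11.30 in 596-6, 1.63 to 13.02 in 596-7 and 3.86 to 11.51 in 596-11. The transactivator rtTA3, WPRE, the bleomycin resistance gene BleoR and 3LTR were also called up in all 5 comparisons. PuroR was called in 596-7 (2.93 on NextSeq, adjusted p = 2.34e-05, and 3.14 on NovaSeq, 0.00316) and missed the threshold in 596-11 (2.95, 0.0517). RRE was called in 596-11 (3.19, adjusted p = 0.0284) and in the average over clones (0.99, 0.0352), but only treated 596-11 reached a log2 CPM above 0 (mean 0.30). AmpR and ori were not called in any. RFP differed between clones in its rise (interaction adjusted p = 8.21e-08), as did, among others, BleoR (0.000958), rtTA3 (0.000718) and WPRE (0.0121). Treated RFP values lie at the top of quantile normalized tables, where they follow rank. They were the same in both treated libraries of 596-6 (11.30) and in both of 596-11 (11.51). The labels of treated and untreated libraries of 596-7 are thus matched by the reporter while EFNB2 runs against the silencing label.

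**Figure D1:**
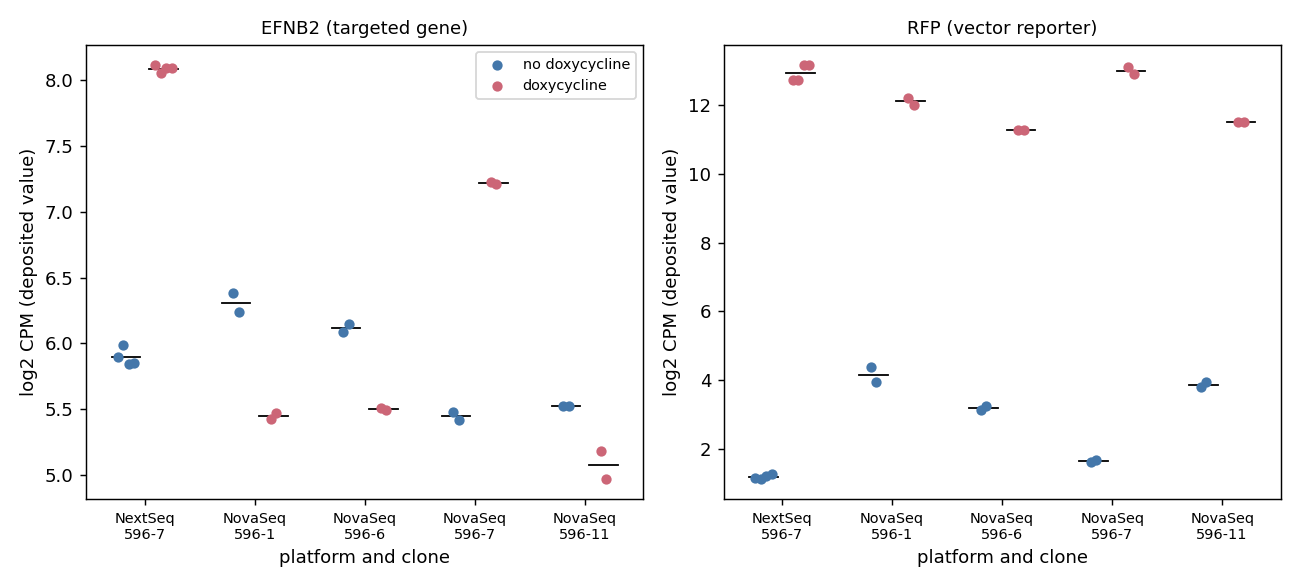
Deposited log2 CPM of EFNB2 and of the vector reporter RFP in every library, with group means as bars. EFNB2 fell with doxycycline in 3 NovaSeq clones and rose in 596-7 on both platforms, and RFP rose in all.

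How did 596-7 respond on NextSeq? The libraries labelled as treated showed an antiviral and inflammatory programme and a stress programme. Lists of cell cycle and ribosomal protein genes were called down as well, but not with an estimated correlation (adjusted p = 0.0745 for replication, 0.107 for mitosis and 0.398 for cytosolic ribosomal proteins). The ribosomal protein median turns from -0.79 to 0.10 when libraries are centred on those genes. Of 13674 human genes tested 11996 were called, 5540 up and 6456 down, and 3032 and 3440 of these changed at least 2-fold. The largest rises were MMP13 (log2 fold change 11.00), a collagenase, and the antiviral genes RSAD2 (10.23), TRIM22 (8.97), ZBP1 (8.78), MX2 (8.56), XAF1 (8.43) and HERC5 (8.18). Among them were also the interferon genes IFNB1 (8.64, adjusted p = 5.82e-10) and IFNL1 (8.43, 2.43e-10) and the chemokine CCL5 (8.20). Untreated means of MMP13 (log2 CPM -2.18) and TRIM22 (-2.19) lay near the floor of the table, where the size of a fold depends on that floor. Among the largest falls were the nuclear receptor NR0B2 (-6.51), the hypoxia-linked MIR210HG (-6.43), UGT1A8 (-5.98), SOSTDC1 (-5.83), RDM1 (-5.79), PI3 (-5.63), the histone HIST2H3C (-5.60, adjusted p = 0.0165), NOX1 (-5.59) and GABRP (-5.55). UGT1A8 shares exons with its paralogs and histone copies resemble each other, so reads for these are hard to assign, and 4 loci without a gene name were passed over among the falls. Robust eBayes ended the call of HIST2H3C (adjusted p = 0.0566).

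Of 32 lists 17 were called in NextSeq 596-7, 9 up and 8 down, and adjusted over the list alone each of them had the same number of members passing. All 44 interferon-stimulated genes rose (median log2 fold change 5.90, adjusted p = 7.61e-17, 0.00812 with an estimated correlation), MX1 (7.69) and IFIT2 (7.58) among the lowest p-values. In the integrated stress response list of ATF4 targets 34 of 35 rose and 1 fell (median 2.30, adjusted p = 2.49e-10, 0.0133 with an estimated correlation), among them ATF3 (5.68), SESN2 (4.48) and TRIB3 (4.31). NF-kappaB and chemokine genes rose in 21 of 22 cases (median 3.51, 7.48e-07, 0.0133 with an estimated correlation), for instance CFB (4.91) and IL1A (5.61). MAPK output and immediate-early genes rose in 27 of 31 and fell in 4 (median 2.17, adjusted p = 2.82e-06, adjusted p = 0.0915 with an estimated correlation), with AREG (3.46) and DUSP5 (3.50). Of 20 YAP/TEAD targets 17 rose and 1 fell (median 2.27, 0.00012, adjusted p = 0.284 with an estimated correlation), GADD45A (3.78) and AJUBA (2.95) first. Antigen presentation genes were up in 11 of 14 and down in 1 (median 1.83, 0.000349, adjusted p = 0.284 with an estimated correlation), led by TAP1 (4.21) and NLRC5 (5.45). Among 22 p53 targets 14 rose and 6 fell (median 1.06, 0.0168, adjusted p = 0.284 with an estimated correlation), including CDKN1A (3.16) and GDF15 (3.43). Mesenchymal markers were up in 7 of 9 and down in 1 (median 3.33, 0.0181, adjusted p = 0.155 with an estimated correlation), such as TNC (3.57) and AXL (3.95). The 5 enteroendocrine markers, SYP (2.35) and SCG5 (2.85) among them, rose as well (median 2.35, 0.0393, adjusted p = 0.232 with an estimated correlation).

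What fell in 596-7 on NextSeq was led by proliferation. All 35 DNA replication genes fell (median -2.39, adjusted p = 9.36e-10, adjusted p = 0.0745 with an estimated correlation), including RRM2 (-3.93). All 34 mitosis genes fell too (median -1.77, 2.87e-09, adjusted p = 0.107 with an estimated correlation), including BUB1B (-2.79) and TOP2A (-2.84). Replication-dependent histones fell in 52 of 61 cases and rose in 5 (median -1.66, 6.26e-07, adjusted p = 0.284 with an estimated correlation), with HIST1H1B at -3.21 and HIST2H4B at 4.60. Respiratory chain genes of the nucleus fell in 49 of 53 (median -1.19, 2.57e-07, adjusted p = 0.398 with an estimated correlation), UQCRH (-2.72) and SDHA (-1.88) first. Cytosolic ribosomal protein genes fell in 74 of 77 (median -0.79, 3.82e-09, adjusted p = 0.398 with an estimated correlation), RPL7A (-2.59) and RPL6 (-1.82) at the lowest p-values, a direction that flips by construction once libraries are centred on these genes (median 0.10). Of 78 mitochondrial ribosomal protein genes 62 fell and 9 rose (median -0.67, 2.63e-05, adjusted p = 0.398 with an estimated correlation), among them MRPL42 (-2.35) and MRPS27 (-2.15), and this median too flips under that centring (0.22). Cholesterol genes fell in 18 of 25 and rose in 3 (median -0.95, 0.0162, adjusted p = 0.329 with an estimated correlation), HMGCS1 rising by 2.00. In the hypoxia and glycolysis list 18 of 29 fell and 6 rose (median -0.49, 0.0462, adjusted p = 0.409 with an estimated correlation), GPI (-3.08) and CA9 (-4.22) among the falls, and centring on ribosomal protein genes turned the median to 0.41.

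The other 15 lists were not called in NextSeq 596-7, although many of their members changed one by one. Ephrins and Eph receptors went both ways, 7 of 15 up and 8 down (median -0.37, mean 0.07, test up, adjusted p = 0.92), EPHB4 (-2.33) at the lowest p. Of 13 mitochondrially encoded mRNAs 12 fell (median -1.39, 0.0714), among them MT-CO2 (-1.40), and in the RNA interference machinery 7 of 13 fell and 4 rose (-0.31, 0.595), AGO1 at -2.23. Differentiation lists leaned down without passing: enterocyte markers 9 of 13 down and 3 up (median -1.27, 0.131), goblet markers 13 of 20 down and 5 up (-1.34, 0.197). Stem cell markers went down in 7 of 11 and up in 4 (-1.06, 0.376), and epithelial junctions and keratins down in 21 of 36 and up in 13 (-0.37, 0.595). KLF4, a goblet list member, rose by 4.20 on the log2 scale. Wnt targets were split 8 up and 9 down of 17 (median -0.59, 0.98), Notch genes 10 up and 4 down of 14 (0.65, 0.0887), and homeobox genes 6 up and 14 down of 24 (-0.46, 0.261). NRF2 targets had 11 up and 17 down of 30 (-0.97, 0.387), metallothioneins 2 up and 4 down of 6 (-3.62, 0.283), and abundant noncoding RNAs 9 up and 1 down of 24 (0.24, 0.232). The unfolded protein response of the ER had 7 up and 12 down of 21 (median -0.42, mean 0.17, test down, 0.65) and imprinted genes 4 up and 4 down of 8 (median -0.28, mean -0.01, test up, 0.92). Cancer-testis antigens (1 gene) and markers of fibroblasts (3), blood cells (4) and endothelium (3) had too few measured members to be tested.

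Scaling matters for the size of the falls in 596-7 on NextSeq. With libraries centred on ribosomal protein genes the median of all genes shifts by 0.90 and 74.9% of calls are up rather than 46.2%. Those genes were themselves called down on the deposited scale, and nothing here shows which scale is right. The second untreated NextSeq library stood apart by its share of mitochondrial mRNA (1.72%, against 0.741% to 0.993% in the other untreated and 0.465% to 0.491% in the treated libraries), and leaving out any 1 library ended 0 of the 56 named calls.

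Was the 596-7 response the same on NovaSeq? There 10595 genes were called, 4542 up and 6053 down (2439 and 3039 at least 2-fold). Of the 17 lists called on NextSeq 13 were called on NovaSeq in the same direction and 1, the enteroendocrine markers, was not tested there. Antigen presentation (adjusted p = 0.0820), p53 targets (0.0630) and hypoxia genes (0.116) were not called on NovaSeq, and homeobox genes were called only there. Of 13382 genes tested in both tables, 11718 were called on NextSeq, and 10860 of these (92.7%) had the same sign on NovaSeq. A total of 9387 genes were called in both tables, 9096 with the same sign and 291 with opposite signs; 4014 were up in both (1731 expected for independent lists) and 5082 down in both (2692 expected). Fold changes correlated across genes (Pearson r = 0.887, Spearman rho = 0.906), which describes genes that are not independent replicates. MX1 rose by 7.69 and 6.33 (NextSeq, then NovaSeq), IFIT2 by 7.58 and 3.84, ATF3 by 5.68 and 7.37, MMP13 by 11.00 and 9.62, RSAD2 by 10.23 and 7.33 and SESN2 by 4.48 and 5.44. Whether both platforms read the same RNA is not stated.

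On NovaSeq, the largest rises of 596-7 were SPX (11.60), IL1RL1 (11.25) and the drug efflux pump ABCB1 (10.22), and the largest falls LINC00261 (-7.17), MIR210HG (-6.27) and NEURL1B (-6.24), after 4 falls without a gene name were passed over. Of 30 lists 14 were called. Interferon-stimulated genes rose in 41 of 44 and fell in 2 (median 3.81, adjusted p = 2.57e-19, 0.0292 with an estimated correlation), MX1 (6.33) and DDX58 (5.07) for example. Stress response genes rose in 32 of 35 and fell in 2 (2.84, 5.18e-14, 0.00132 with an estimated correlation), CHAC1 (7.54) and TRIB3 (5.28) among them. MAPK output rose in 26 of 30 and fell in 3 (1.91, 1.57e-07, 0.0152 with an estimated correlation), DUSP5 (4.55) and AREG (4.00) included, and NF-kappaB genes rose in 19 of 22 and fell in 3 (2.98, 4.31e-06, 0.0221 with an estimated correlation), TNFAIP3 at 4.86. YAP/TEAD targets rose in 15 of 20 and fell in 1 (1.89, 3.43e-06, adjusted p = 0.18 with an estimated correlation), GADD45A (4.00) among them. Mesenchymal markers rose in 8 of 10 and fell in 1 (1.70, 0.00329, adjusted p = 0.113 with an estimated correlation), with AXL (4.88) and TNC (5.05). The 34 mitosis genes all fell (-1.57, 5.25e-10, adjusted p = 0.247 with an estimated correlation), as did 34 of 35 replication genes (-1.43, 5.61e-10, adjusted p = 0.139 with an estimated correlation), CENPF (-2.17), KIF20A (-2.36), MCM4 (-1.61) and UNG (-1.96) among them.

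Also down in NovaSeq 596-7 were 41 of 53 respiratory chain genes (median -0.87, adjusted p = 9.23e-05, adjusted p = 0.644 with an estimated correlation), SDHA at -1.37. Mitochondrial ribosomal protein genes fell in 58 of 78 and rose in 5 (-0.61, 0.000232, adjusted p = 0.644 with an estimated correlation), MRPS34 at -1.70. Cytosolic ribosomal protein genes fell in 54 of 77 (-0.48, 0.000115, adjusted p = 0.644 with an estimated correlation), RPS15 by -1.24, and flip to a median of 0.06 when libraries are centred on them. Histones fell in 38 of 62 and rose in 6 (-0.76, 0.00168, adjusted p = 0.605 with an estimated correlation), with HIST1H3C (-1.87) and again HIST2H4B (3.88). Cholesterol genes fell in 19 of 25 and rose in 3 (-0.79, 0.00667, adjusted p = 0.247 with an estimated correlation), HMGCS1 (1.99) rising as on NextSeq. Homeobox genes fell in 18 of 25 and rose in 2 (-0.74, 0.0392, adjusted p = 0.586 with an estimated correlation), HOXA13 among them. Adjusted over the list alone, the counts passing moved by 1 or 0 members in every called list. Centring on ribosomal protein genes shifts the median of all genes by 0.53 and makes 68.8% of calls up rather than 42.9%. The first untreated 596-7 library on NovaSeq had more mitochondrial mRNA (1.05% against 0.439%) and PuroR (log2 CPM 5.53 against 3.91) than the second, and leaving out any 1 library ended 0 of the 35 named calls.

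Which changes appear in the average over the clones? Averaged over the 4 NovaSeq clones, 8438 genes were called, 3614 up and 4824 down, but few were large (504 up and 118 down at least 2-fold), and 596-7 weighs in the mean: without it 2719 genes were called, 2337 of them shared. Rises in the same direction in all 4 clones were largest for the serine protease TMPRSS11E (5.84), SPX (4.80), MMP13 (4.44), BLOC1S5-TXNDC5 (3.67, adjusted p = 0.0118), THSD7A (3.52), the elastase CELA3B (3.40), PNPLA1 (3.39), ALOXE3 (3.35), the potassium channel KCNF1 (3.26) and the interferon-induced IFI44L (3.20). Falls were largest for LINC02532 (-2.37), ceruloplasmin CP (-1.82, adjusted p = 0.00258), NEURL1B (-1.80), annexin ANXA13 (-1.79), MIR210HG (-1.74), PPFIA4 (-1.70), LINC02038 (-1.69), CBLN1 (-1.66), LHFPL3-AS2 (-1.64) and FAM83C (-1.54), with 2 unnamed loci passed over. BLOC1S5-TXNDC5 is a readthrough and CELA3B has a near copy, so their reads are hard to assign. Without 596-7, PNPLA1 (adjusted p = 0.0746), NEURL1B (0.188), MIR210HG (0.643), PPFIA4 (0.501) and LINC02038 (0.178) were no longer called.

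In the average over clones 16 of 30 lists were called. Without 596-7 only 8 of these stayed called, and those lost were NF-kappaB genes (adjusted p = 0.167), mesenchymal markers (0.378), p53 targets (0.0646), mitosis (0.180), replication (0.885), the respiratory chain (0.0646), cholesterol (0.106) and histones (0.716). Those kept then had smaller medians, 0.92 for interferon-stimulated genes, 0.22 for antigen presentation and 0.23 for YAP/TEAD targets, and near 0 for MAPK output (0.09) and the stress response (0.06). Among those that fell the medians were -0.15 and -0.12 for mitochondrial and cytosolic ribosomal proteins and -0.14 for hypoxia. Interferon-stimulated genes were up in 42 of 44 and down in 2 (median 1.62, adjusted p = 1.97e-27, 0.0138 with an estimated correlation), DDX58 (2.19) and MX1 (2.52) first. Stress response genes were up in 28 of 35 and down in 3 (0.76, 5.7e-13, 0.00176 with an estimated correlation), TRIB3 (1.77) and CHAC1 (2.74) first. MAPK output was up in 26 of 30 and down in 4 (0.56, 1.17e-07, 0.0138 with an estimated correlation), DUSP5 (1.45) and HBEGF (1.81) for example, and NF-kappaB genes in 15 of 22 with 3 down (0.76, 3.97e-05, 0.0312 with an estimated correlation), TNFAIP3 at 1.61. Further lists up, each lost with an estimated correlation, were YAP/TEAD targets (14 up and 2 down of 20, 9.28e-07, adjusted p = 0.131 with an estimated correlation, AJUBA at 1.37) and mesenchymal markers (6 up and 1 down of 10, 0.0076, adjusted p = 0.131 with an estimated correlation). The same applied to antigen presentation (9 up and 2 down of 16, 0.0076, adjusted p = 0.131 with an estimated correlation) and p53 targets (11 up and 4 down of 22, 0.017, adjusted p = 0.2 with an estimated correlation). Mitosis genes fell in 33 of 34 (median -0.45, 1.59e-09, adjusted p = 0.279 with an estimated correlation), KIF20A at -0.77, and replication genes in 31 of 35 (-0.37, 2.84e-08, adjusted p = 0.138 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 52 of 78 (-0.29, 1.04e-06, adjusted p = 0.551 with an estimated correlation), MRPS25 at -0.48. Cytosolic ones fell in 50 of 77 (-0.22, 6.06e-06, adjusted p = 0.643 with an estimated correlation) and respiratory chain genes in 29 of 53 with 1 up (-0.26, 0.000216, adjusted p = 0.672 with an estimated correlation). Cholesterol genes fell in 14 of 25 and rose in 3 (-0.25, 0.0103, adjusted p = 0.295 with an estimated correlation), DHCR7 at -0.64. Histones fell in 31 of 62 and rose in 3 (-0.21, 0.0145, adjusted p = 0.672 with an estimated correlation). Hypoxia genes fell in 16 of 28 and rose in 5 (-0.19, 0.0146, adjusted p = 0.131 with an estimated correlation, median flipping to 0.01 under ribosomal centring), AK4 at -0.72. Adjusted over the list alone 33 stress response and 23 hypoxia genes passed. Ribosomal centring shifts the average's median of all genes by 0.21 and makes 78.4% of calls up rather than 42.8%.

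What did 596-1 do under doxycycline on its own? It raised interferon-stimulated genes, with 562 genes called, 331 up and 231 down (73 and 17 at least 2-fold). TMPRSS11E (7.89), MMP13 (4.07) and GPRIN2 (3.69) rose most, with 1 unnamed locus passed over, and BMP6 (-2.56), CENPS-CORT (-2.16) and PHGR1 (-1.76) fell most. CENPS-CORT is a readthrough whose reads overlap its parts. Leaving out either treated 596-1 library left the BMP6 fold change at -2.56, so its treated values were equal. Values tie at the floor (log2 CPM -6.23 in both treated libraries), and if BMP6 lies there its fold depends on that floor. Of 44 interferon-stimulated genes 36 rose and 0 fell, 42 when adjusted over the list alone (median 0.98, adjusted p = 6.32e-47, 0.00712 with an estimated correlation), DDX58 (1.42), IFIT1 (1.78) and OAS1 (1.24) among them. The other 3 called lists were lost with an estimated correlation, among them antigen presentation (2 of 16 up, 3 over the list alone, median 0.18, 0.0436, adjusted p = 0.31 with an estimated correlation) and enterocyte markers (2 of 12 down, 3 over the list alone, -0.25, 0.0436, adjusted p = 0.255 with an estimated correlation), CEACAM6 at -0.74. Mitochondrial ribosomal proteins were the last of them (3 of 78 down, -0.05, 0.0458, adjusted p = 0.961 with an estimated correlation). The extracellular matrix gene TNC (1.23) and the cell cycle inhibitor CDKN1A (0.64) rose as well. Leaving out 1 library moved the count from 562 to 6533 (second untreated 596-1 library), 206 and 145 (first and second treated 596-1), 316 (either untreated 596-6), 303 (either treated 596-6), 305 (either untreated 596-11) and 330 (either treated 596-11). It ended the calls of BMP6, CENPS-CORT and PHGR1 (highest adjusted p = 0.260, second treated 596-1 library out). A limma fit of its 4 libraries alone called 0 genes, with 540 at an unadjusted p under 0.05, and ribosomal centring left 167 calls (85.6% up rather than 58.9%). The first untreated 596-1 library stood apart in mitochondrial mRNA (1.79% against 0.645%) and PuroR (log2 CPM 8.20 against 5.13).

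In the joint fit 596-6, whose interferon genes were highest before treatment, had the fewest calls, whereas in fits of each clone's own libraries 596-1 had the fewest (0 against 2968). Doxycycline changed 160 genes, 112 up and 48 down (21 and 2 at least 2-fold). TMPRSS11E (5.78), WFIKKN1 (3.96) and CELA3A (3.13) rose most, and ANXA13 (-1.27), the keratin KRT13 (-1.13) and TPPP3 (-0.91) fell most. Of 44 interferon-stimulated genes 20 rose, 35 when adjusted over the list alone (median 0.53, adjusted p = 1.38e-37, 0.0151 with an estimated correlation), with DDX58 (0.66), HERC5 (0.83) and CMPK2 (0.86). Antigen presentation was called up with 1 of 16 members passing, 4 over the list alone (0.23, 3.42e-05, 0.0449 with an estimated correlation). Lists lost with an estimated correlation were mitochondrial ribosomal proteins (median -0.16, 8 of 78 at an unadjusted p under 0.05 and 0 called, adjusted p = 5.24e-07, adjusted p = 0.77 with an estimated correlation) and cytosolic ribosomal proteins (-0.16, 3 of 77 unadjusted and 0 called, 3.2e-06, adjusted p = 0.823 with an estimated correlation). So were NRF2 targets (2 of 30 down including GPX2 at -0.62, median -0.15, 0.00 after ribosomal centring, 0.00254, adjusted p = 0.382 with an estimated correlation) and hypoxia (-0.12, flipping to 0.04 after that centring, 4 of 28 unadjusted and 0 called, 0.0259, adjusted p = 0.309 with an estimated correlation). YAP/TEAD targets (2 up and 1 down of 20, 8 over the list alone, 0.25, 0.00273, adjusted p = 0.561 with an estimated correlation), homeobox genes (0.13, 5 of 25 unadjusted and 0 called, 4 over the list alone, 0.00937, adjusted p = 0.665 with an estimated correlation) and epithelial junctions (1 of 36 up, 4 over the list alone, 0.09, 0.0263, adjusted p = 0.382 with an estimated correlation) leaned up. Without 1 library the count was 39 or 40 (first or second untreated 596-6), 35 or 39 (first or second treated 596-6), 719 or 721 (first or second untreated 596-1) and 101 (either untreated 596-11). Of the 13 named calls 7 ended without some library of 596-6, 5 of them without its first untreated one (highest adjusted p = 0.124). After ribosomal centring, which shifts the median of all genes by 0.16, the clone had 97 calls (93.8% up rather than 70%).

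In 596-11 doxycycline raised interferon-stimulated, stress response, MAPK output and NF-kappaB genes. It changed 765 genes, 448 up and 317 down (155 and 25 at least 2-fold), TERB1 (7.45), IL1RL1 (5.90) and SPX (5.44) rising most and SOX8 (-2.94), SPOCD1 (-2.83) and GUCA1B (-2.43) falling most, after 1 unnamed locus was passed over. Interferon-stimulated genes rose in 40 of 44, 41 over the list alone (median 1.26, adjusted p = 7.86e-59, 0.00161 with an estimated correlation), DDX58 (1.60), OAS1 (1.38) and MX1 (1.78) included. Stress response genes rose in 15 of 35 and fell in 1, 21 over the list alone (median 0.23, mean 0.65, 1.81e-11, 0.00161 with an estimated correlation), with CHAC1 (3.26), ATF3 (4.13) and TRIB3 (1.14). MAPK output rose in 10 of 30 and fell in 1, 13 over the list alone (0.34, 6.64e-10, 0.0036 with an estimated correlation), with EGR2 (3.70) and DUSP5 (0.99). NF-kappaB genes rose in 5 of 22, 11 over the list alone (0.34, 0.000252, 0.0434 with an estimated correlation), TNFAIP3 at 1.49. Antigen presentation rose in 4 of 16 (0.21, 0.000318, 0.0434 with an estimated correlation), with TAP1 (0.63) and NLRC5 (0.88).

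The other 12 called lists of 596-11 were lost with an estimated correlation. Up were YAP/TEAD targets (6 of 20, 13 over the list alone, median 0.36, adjusted p = 2.86e-07, adjusted p = 0.124 with an estimated correlation), AJUBA at 0.97, and p53 targets (5 of 22, 6 over the list alone, 0.03, 0.032, adjusted p = 0.234 with an estimated correlation), CDKN1A at 1.07. So were homeobox genes (1 up and 1 down of 25, 0.22, 0.0153, adjusted p = 0.448 with an estimated correlation), epithelial junctions (3 up and 3 down of 36, 0.13, 0.0132, adjusted p = 0.212 with an estimated correlation) and the unfolded protein response (2 of 21, 0.05, 0.0382, adjusted p = 0.212 with an estimated correlation). Down were mitochondrial ribosomal proteins (3 of 78, -0.22, 5.6e-09, adjusted p = 0.439 with an estimated correlation) and cytosolic ones (1 of 77, -0.20, 3.52e-06, adjusted p = 0.585 with an estimated correlation). The test also put down the respiratory chain (1 of 53 up, median -0.21, 0.000318, adjusted p = 0.655 with an estimated correlation), mitosis (1 of 34, -0.19, 0.000491, adjusted p = 0.539 with an estimated correlation) and cholesterol genes (2 of 25, 5 over the list alone, -0.20, 0.00252, adjusted p = 0.234 with an estimated correlation). Hypoxia genes (2 of 28 down, median -0.16, 0.03 after ribosomal centring, 0.00217, adjusted p = 0.0589 with an estimated correlation) and NRF2 targets (2 up and 3 down of 30, 11 over the list alone, median -0.17, mean 0.02, test down, 0.01 after ribosomal centring, 0.0409, adjusted p = 0.439 with an estimated correlation) flip in sign under that scaling. It shifts the median of all genes in this clone by 0.19 and leaves 497 calls (93.6% up rather than 58.6%). Without 1 library the 765 calls became 255 or 237 (first or second untreated 596-11), 272 or 246 (first or second treated 596-11) and 2288 or 2286 (first or second untreated 596-1). SOX8, SPOCD1 and GUCA1B lost their calls (highest adjusted p = 0.296, SOX8 without the first treated 596-11 library). Fitted on its own 4 libraries 596-11 had 5645 calls.

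**Figure D2:**
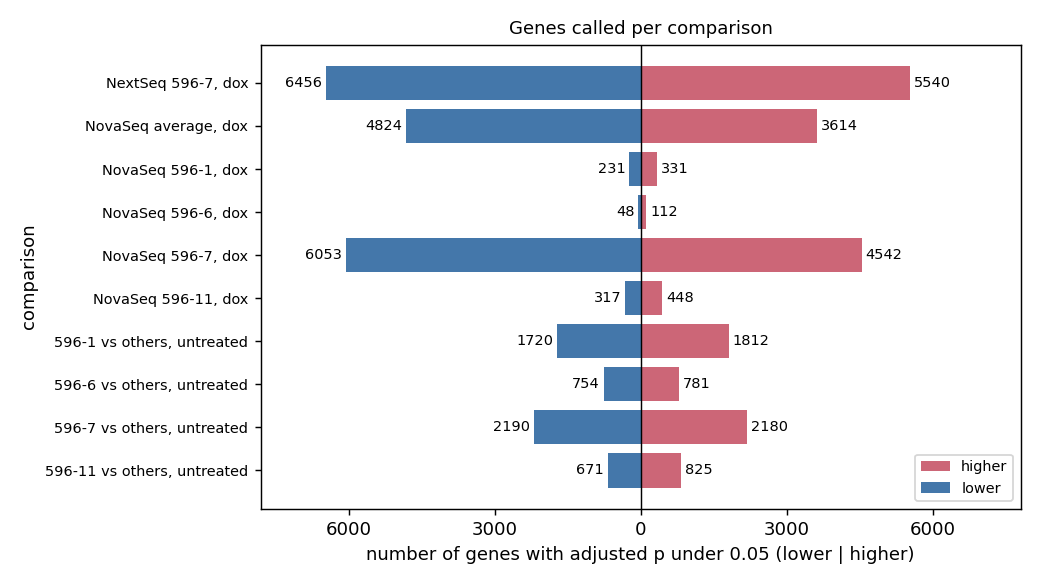
Human genes called higher and lower (adjusted p under 0.05) in each comparison with doxycycline and in each untreated clone against the other 3. Shares of higher and lower calls with doxycycline move towards higher when libraries are centred on ribosomal protein genes.

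Do the clones share a response? Calls overlapped far more than independent lists would: 196 genes rose in both 596-1 and 596-11 (10.3 expected, Fisher adjusted p = 2.19e-221), 99 in both 596-1 and 596-6 (2.58 expected, 1.57e-152) and 99 in both 596-6 and 596-11 (3.50 expected). With 596-7 the shared rises were 234 for 596-1 (105 expected), 87 for 596-6 (35.5 expected) and 403 for 596-11 (142 expected). Shared falls numbered 41, 117 and 39 between 596-1 and 596-6, 596-1 and 596-11, and 596-6 and 596-11, against 0.773, 5.10 and 1.06 expected. In all 4 clones 77 genes rose (0.0255 expected), 20 of them interferon-stimulated, and 31 fell (0.0072 expected). The clones share 1 estimate of spread per gene and genes are not independent draws, so these expected numbers and Fisher p-values are only a rough guide. Ribosomal centring left 97 calls in 596-6, 93.8% of them up, so most falls shared with that clone are not called there under that scaling. Of 3 shared rises picked after their values were seen, TPBG (1.91 in 596-1, 1.83 in 596-6, 2.11 in 596-7 and 1.63 in 596-11, interaction adjusted p = 0.0196) and the complement regulator CD55 (1.78, 1.62, 2.32 and 1.87, 0.0169) differed in size between clones. For TGFBI (0.65, 0.71, 0.57 and 0.72, 0.677) no difference was detected. TGFBI was no longer called in 596-1, 596-6 and 596-11 after ribosomal centring.

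Although genes were shared, the size of the response differed between clones for 8248 genes by the interaction test, and for 39 with 596-7 left aside. TRIB3 (adjusted p = 4.43e-10), SLFN5, ETS1, PPP1R15A, FILIP1L and SPIRE1 (each 4.70e-10) had the lowest p-values; of these SLFN5 (0.119) and ETS1 (0.0663) were not called without 596-7. Of the 4 clones TRIB3 rose most in 596-7 (5.28) and next in 596-11 (1.14), while PPP1R15A encodes the subunit that ends the stress response. By list level 22 of 30 lists responded differently between clones, the stress response (adjusted p = 6.69e-11), interferon (4.20e-09), mesenchymal and replication lists (each 2.67e-08) most. The interferon list's median log2 CPM went from 4.56 to 5.53 in 596-1, 6.51 to 6.97 in 596-6, 2.96 to 6.74 in 596-7 and 4.93 to 6.04 in 596-11, and from 3.67 to 9.28 in 596-7 on NextSeq. For the stress response list the levels were 5.44 and 5.36, 5.22 and 5.40, 5.08 and 8.89, and 5.51 and 5.82 in the same order, and 5.46 and 8.60 on NextSeq.

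**Figure D3:**
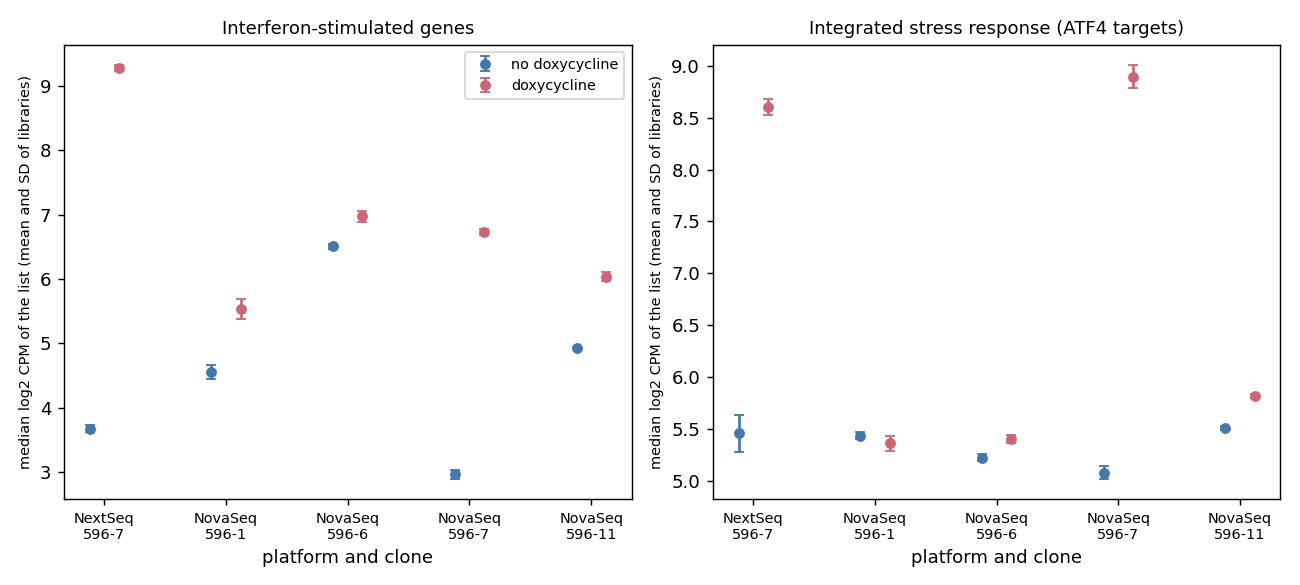
Median log2 CPM of 2 gene lists in each group (mean and SD of the libraries). The interferon list rose in every clone and the stress response list was called up in 596-7 and 596-11.

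How far apart were the clones before treatment? By the F test 5089 genes differed among the 4 untreated clones, 2819 with 596-7 left aside. Leaving out the second untreated 596-1 library gave 10324. EFNB2 itself differed, being higher in 596-1 (0.61 above the mean of the others, adjusted p = 4.55e-05) and 596-6 (0.35, 0.00343) and lower in 596-7 (-0.54, 6.62e-05) and 596-11 (-0.43, 0.00133). Among treated libraries EFNB2 was lower in 596-1 (-0.49), 596-6 (-0.41) and 596-11 (-0.98) and higher in 596-7 (1.88), and without the second untreated library of 596-6 the untreated difference of that clone was not called (adjusted p = 0.0756). Each contrast uses the other 3 clones as its reference, so a clone that lies far out moves the differences of the rest.

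Untreated 596-1 lay below the mean of the other clones in enterocyte markers, as did untreated 596-6, with 3532 genes differing in 596-1, 1812 higher and 1720 lower. Highest above the others were CLEC3A (5.39), the collagen COL14A1 (5.16), the invariant chain CD74 (4.96), LY6D (4.78), WWTR1 (4.71), which encodes the TEAD partner TAZ, and SIRPA (4.65). Lowest were the potassium channel KCNJ2 (-5.59), GPRIN2 (-5.30), the transporter SLCO2B1 (-4.81), AKAP2 (-4.52), SYNE3 (-4.18) and CADPS2 (-4.08), with 2 unnamed loci passed over. Enterocyte markers were lower in 8 of 12 (median -1.21, adjusted p = 2.17e-06, 0.014 with an estimated correlation), CEACAM6 (-1.94) and HNF4A (-1.30) among them. The other called lists were lost with an estimated correlation. Higher were mesenchymal markers (6 of 10, 2 lower, 1.32, 0.00146, adjusted p = 0.15 with an estimated correlation), AXL (2.27) and TNC (2.31) first, and YAP/TEAD targets (8 of 20, 3 lower, 12 over the list alone, 0.35, 0.00474, adjusted p = 0.549 with an estimated correlation). Also higher were ephrins and Eph receptors (6 of 14, 2 lower, 0.27, 0.0127, adjusted p = 0.652 with an estimated correlation), EPHB2 at 1.24, and imprinted genes (3 of 8, 0.29, 0.0297, adjusted p = 0.549 with an estimated correlation). Lower, but with a median that turns positive after ribosomal centring in each case, were interferon-stimulated genes (20 of 44, 2 higher, median -0.25, 0.00114, adjusted p = 0.549 with an estimated correlation), STAT2 at -0.67, and goblet markers (8 of 22, 2 higher, -0.25, 0.0234, adjusted p = 0.18 with an estimated correlation), SPINK1 at -2.79, followed by the stress response (9 of 35, -0.05, 0.0288, adjusted p = 0.228 with an estimated correlation). The same holds for cytosolic ribosomal proteins (9 of 77, -0.25, 9.52e-06, adjusted p = 0.796 with an estimated correlation), the respiratory chain (7 of 53, -0.25, 0.00146, adjusted p = 0.796 with an estimated correlation) and mitochondrial ribosomal proteins (6 of 78, -0.16, 0.0127, adjusted p = 0.796 with an estimated correlation). That centring shifts the median of all genes by 0.29 and makes 83.8% of differences positive rather than 51.3%, and without the second untreated 596-1 library 8424 genes differed.

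Interferon genes set untreated 596-6 apart. It had 1535 differing genes, 781 higher and 754 lower. IFITM1 (5.95), IFI44L (5.66), ZNF567 (5.47), WDR72 (4.74), TRIM22 (4.43) and OAS2 (4.31) were highest above the others, and C3orf14 (-6.93), the chemokine receptor CXCR4 (-6.49), PTPRG-AS1 (-5.98), C1QTNF3-AMACR (-5.32), the proteoglycan CSPG4 (-4.89) and the protocadherin PCDHGC3 (-4.59) lowest. C3orf14 and PTPRG-AS1 lie at 1 locus and C1QTNF3-AMACR is a readthrough, whose call ended without the first or the second untreated 596-6 library. Its difference stayed at -5.32 without either, so its values in these libraries were equal. If they lie at the floor (log2 CPM -6.23 in both), the size of the difference depends on that floor. All 44 interferon-stimulated genes were higher (median 2.29, adjusted p = 2.69e-82, 0.000545 with an estimated correlation), IFI6 (3.68) and MX1 (3.55) first, as were 14 of 16 antigen presentation genes (1.03, 5.43e-18, 0.000545 with an estimated correlation), TAP1 (1.63) and PSMB9 (2.88) among them. Enterocyte markers were lower in 7 of 12, 8 over the list alone (-1.01, 9.85e-10, 0.00141 with an estimated correlation), with CEACAM6 (-1.59) and CEACAM5 (-2.18). Goblet markers were lower in 9 of 22, 11 over the list alone (-0.37, 7.37e-07, 0.00297 with an estimated correlation), REG4 at -2.33, and hypoxia genes in 9 of 28, 1 higher (-0.18, 7.24e-05, 0.0189 with an estimated correlation), NDRG1 at -2.02.

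Another 9 lists called in untreated 596-6 were lost with an estimated correlation. Lower were histones (16 of 62, 24 over the list alone, median -0.23, adjusted p = 9.85e-10, adjusted p = 0.258 with an estimated correlation) and cholesterol genes (5 of 25, 10 over the list alone, -0.21, 7.33e-06, adjusted p = 0.0883 with an estimated correlation). Lower too were mitosis (2 of 34, -0.14, 0.000211, adjusted p = 0.585 with an estimated correlation) and NRF2 targets (11 of 30, 1 higher, -0.11, 0.00146, adjusted p = 0.258 with an estimated correlation), AKR1B10 at -2.25. The remaining lower lists were p53 targets (5 of 22, -0.05, 0.0305, adjusted p = 0.258 with an estimated correlation), Notch genes (3 of 16, -0.03, 0.0395, adjusted p = 0.448 with an estimated correlation) and epithelial junctions (6 of 36, 2 higher, -0.08, 0.0497, adjusted p = 0.288 with an estimated correlation). NF-kappaB genes (6 of 22, 1 lower, 11 over the list alone, 0.20, 0.000917, adjusted p = 0.055 with an estimated correlation), CFB at 1.73, and replication genes (4 of 35, 0.08, 0.0237, adjusted p = 0.585 with an estimated correlation) were higher. Without 1 library the count of differing genes in 596-6 was 713 or 687 (its first or second untreated library) and 2726 or 4089 (first or second untreated 596-1).

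Untreated 596-7 was low in interferon genes and high in differentiation markers, with 4370 differing genes, 2180 higher and 2190 lower. IGFBP2 (7.82), the coactivator PPARGC1A (7.26), CSPG4 (6.82), MAGEA12 (6.43), CSAG1 (6.29) and REG4 (6.28) stood highest above the others, after 1 unnamed locus was passed over, and CLEC3A (-11.16), IFITM1 (-8.41), NNMT (-7.47), MIR205HG (-7.31), IFI44L (-6.71) and XAF1 (-6.69) lowest. MAGEA12 and CSAG1 share a locus with near copies. Of 44 interferon-stimulated genes 43 were lower (median -2.27, adjusted p = 6.96e-45, 0.00276 with an estimated correlation), UBE2L6 (-5.68) and CMPK2 (-4.04) included, and 15 of 16 antigen presentation genes (-1.08, 1.95e-12, 0.00276 with an estimated correlation), TAP1 (-2.19) and HLA-B (-2.27) included. Enterocyte markers were higher in 11 of 12 and lower in 1 (1.59, 5.5e-08, 0.00276 with an estimated correlation), CEACAM6 (4.07) and HNF4A (1.85) first. Goblet markers were higher in 14 of 22 with 2 lower, 17 over the list alone (1.08, 4.28e-05, 0.00798 with an estimated correlation), TFF1 at 1.73.

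Lists lost with an estimated correlation in untreated 596-7 were, on the higher side, mitochondrial ribosomal proteins (24 of 78, 1 lower, median 0.26, adjusted p = 5.51e-05, adjusted p = 0.635 with an estimated correlation), cytosolic ones (7 of 77, 2 lower, 0.21, 0.00485, adjusted p = 0.757 with an estimated correlation) and the respiratory chain (10 of 53, 2 lower, 0.24, 0.00485, adjusted p = 0.757 with an estimated correlation). The higher side also held hypoxia (9 of 28, 1 lower, 0.19, 0.00686, adjusted p = 0.0919 with an estimated correlation), NDRG1 at 1.27, and NRF2 targets (15 of 30, 5 lower, 23 over the list alone, 0.26, 0.0186, adjusted p = 0.412 with an estimated correlation), AKR1B10 at 2.99. The stress response was higher as well (12 of 35, 2 lower, 0.15, flipping to -0.03 after ribosomal centring, 0.0238, adjusted p = 0.13 with an estimated correlation). Lower were NF-kappaB genes (8 of 22, 1 higher, -0.33, 0.00249, adjusted p = 0.0816 with an estimated correlation) and YAP/TEAD targets (10 of 20, 2 higher, -0.31, 0.00558, adjusted p = 0.412 with an estimated correlation). Ribosomal centring shifts the median of all genes in this contrast by -0.18 and leaves 25.6% of differences positive rather than 49.9%. Without the second untreated 596-1 library 7684 genes differed in 596-7.

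Untreated 596-11 had 1496 differing genes, about as many as 596-6, 825 higher and 671 lower. MAP9 (9.30), RGS17 (6.65), PIPOX (6.62), KCNJ2 (5.75), IL7 (4.13) and ROBO2 (4.10) were highest above the others, with 1 unnamed locus passed over. PRPS2 (-8.65), an enzyme of nucleotide synthesis, and the zinc finger genes ZNF585B (-8.29), ZNF429 (-6.91), ZNF585A (-6.57) and ZNF383 (-6.30) were lowest together with MAGEA12 (-6.23), and the ZNF585 copies resemble each other. All 8 called lists were lost with an estimated correlation. Higher were mitosis genes (13 of 34, 22 over the list alone, median 0.27, adjusted p = 6.08e-11, adjusted p = 0.364 with an estimated correlation), ANLN at 0.38, and histones (16 of 62, 28 over the list alone, 0.28, 2.74e-10, adjusted p = 0.364 with an estimated correlation), HIST2H2AB at 0.40. Interferon-stimulated genes were higher too (14 of 44, 0.21, 2.02e-09, adjusted p = 0.258 with an estimated correlation), UBE2L6 (1.32) and XAF1 (2.18) among them. Antigen presentation (5 of 16, 1 lower, 0.16, 0.0234, adjusted p = 0.258 with an estimated correlation), CD74 at -4.91, and enterocyte markers (5 of 12, 1 lower, 0.44, 0.0325, adjusted p = 0.258 with an estimated correlation) were higher as well. Lower were replication genes (12 of 35, -0.13, 0.000643, adjusted p = 0.542 with an estimated correlation) and MAPK output (3 of 30, 1 higher, 9 over the list alone, -0.17, 0.0242, adjusted p = 0.258 with an estimated correlation), DUSP5 at -0.67. So were mitochondrial ribosomal proteins (5 of 78, 1 higher, -0.07, 0.0325, adjusted p = 0.931 with an estimated correlation). Without 1 library the count was 440 or 439 (first or second untreated 596-11) and 2941 or 4131 (first or second untreated 596-1).

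Did differences between untreated clones follow chromosomes? In 596-1 the 766 genes of chromosome 12 were lower (28 higher and 380 lower, median -0.41, adjusted p = 1.28e-19, 0.00276 with an estimated correlation), ERBB3 (-1.24) and GALNT6 (-2.62) among them. By position the fall held over the first 90 Mb, with bin medians of -0.52 to -0.78, weakened to -0.28 at 90 to 100 Mb and was -0.11 or closer to 0 beyond. In 596-7 the genes of chromosome 11 were lower (22 higher and 454 lower, median -0.38, 2.99e-26, 7.63e-05 with an estimated correlation), with medians of -0.13 to -0.45 in all bins. Those of chromosome 7 were lower as well (49 higher and 307 lower of 742, -0.29, 9.51e-13, 0.000879 with an estimated correlation), FAM131B at -2.37. Chromosome 11 was called higher in 596-1 (264 higher and 35 lower of 823, 0.18, 8.82e-09, 0.00276 with an estimated correlation), SYT12 at 2.43. It was also called in 596-6 (98 and 20, 0.11, 8.59e-05, 0.0310 with an estimated correlation) and in 596-11 (94 and 21, 0.12, 0.0284 with an estimated correlation), which mirrors 596-7 in their shared reference. Of 23 chromosomes tested 10, 3, 4 and 8 were called in 596-1, 596-6, 596-7 and 596-11, and 2, 1, 2 and 1 with an estimated correlation. Among treated libraries chromosome 12 was again lower in 596-1 (median -0.31, 7.95e-09, 0.0352 with an estimated correlation) and chromosome 11 in 596-7 (-0.70, 0.000127, 0.0346 with an estimated correlation). Chromosome 7 in 596-7 was not called among treated libraries (-0.33, adjusted p = 0.554, 0.901 with an estimated correlation).

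**Figure D4:**
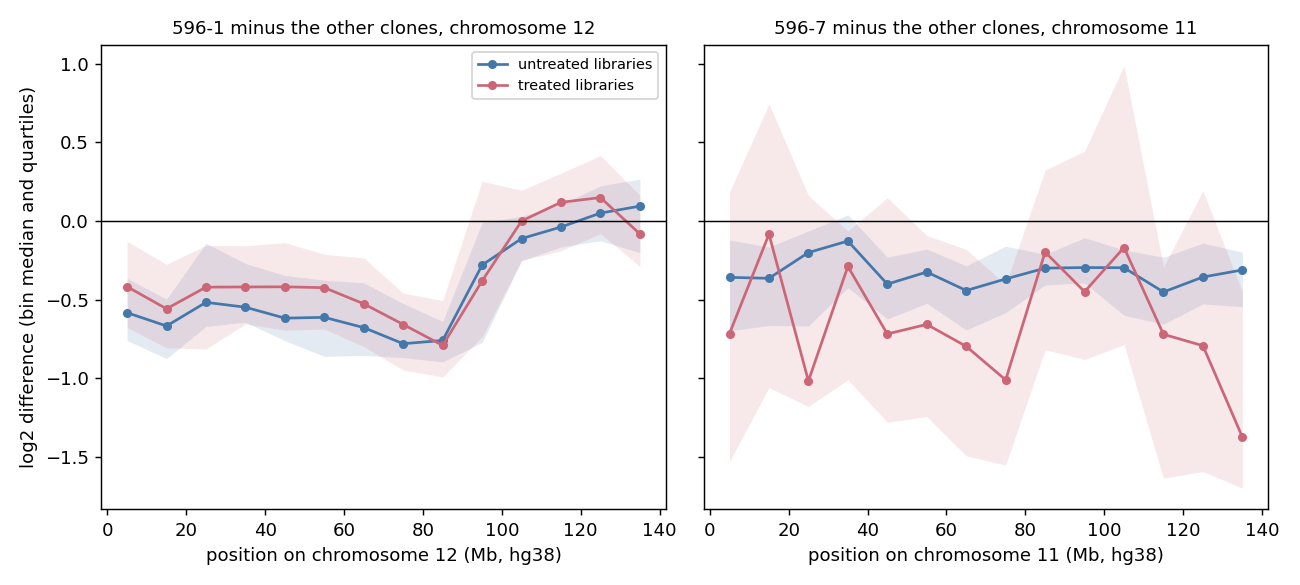
Median log2 difference of genes in bins of 10 Mb along chromosome 12 for 596-1 and chromosome 11 for 596-7, each against the mean of the other 3 clones, in untreated and treated libraries. Bands span the quartiles of the genes in a bin.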

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

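Among the tests of this part, the percentile of EFNB2 among genes of similar level, the count without the libraries that stand apart and the other splits of libraries were set beforehand. The tests on RFP, on a common shift, on the number of clones, on treated interferon levels and on starting levels were chosen after the result was seen.

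EFNB2 responded to doxycycline differently between clones (interaction adjusted p = 2.84e-08), higher in the treated libraries of 596-7 and lower in the other 3 clones. An exchange of labels in 596-7 is argued against by RFP, whose lowest treated library lay 11.26 log2 units above the highest untreated one in the table with the smaller gap. Among the 500 genes nearest in level EFNB2 sat at percentile 94.8 on NextSeq and 95.6 on NovaSeq, inside the range set beforehand for a shift of the scale, so that test did not set it apart from other genes of a clone in which most genes moved. One common shift of such genes, a measure picked afterwards, is argued against by their median of -0.10 on NextSeq (1.71 SD below EFNB2, and 1.93 SD on NovaSeq). A response of the endogenous gene in 596-7 is a candidate explanation. EFNB2 was higher in only 1 of 4 clones, which this explanation allows but which does not show it. The values do not separate endogenous from other EFNB2 reads, so these cannot be told apart.

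The response of 596-7 was larger than those of the other clones. Libraries that stand apart are argued against as the whole account, since without the first untreated libraries of 596-1 and 596-7 its count was still 2.34 times the largest other count (11875 against 5078). With all libraries it was 10595 against 765, from a spread shared by all clones. Limma fits of each clone's own libraries moved the genes at an unadjusted p under 0.05 from 2744 to 7066 in 596-11. In the clone with the fewest calls of the joint fit they went from 1720 to 5450. They went from 2801 to 540 in 596-1 and from 10843 to 10528 in 596-7. The counts of the other clones thus depend on the spread used, and how far this accounts for their moves was not tested. Also argued against is a different starting level of the responding genes as a whole, since before treatment its called genes lay away from the other clones, against the direction of the response, by a median share of only 0.0174 of that response (quartiles -0.190 and 0.243). A lower interferon level before treatment may account for some of the interferon part, where that share was 0.631 (quartiles 0.478 and 0.797). The list ended in treated 596-7 at -0.24 relative to the highest other treated clone, which was also the highest before treatment. It ended higher in treated 596-7 than in treated 596-1 and 596-11. A lower start therefore leaves part of the difference from those clones open. Higher vector transcription remains possible for part of the vector. RFP in the lowest treated 596-7 library was 0.68 above the highest treated library of any other clone. After quantile normalization such a value follows the rank of the feature in its library. RFP was the same in both treated libraries of 596-6 (11.30) and in both of 596-11 (11.51). The gap therefore shows a higher rank near the top of the table and not a measured amount. Treated 596-7 was also higher in, among others, BleoR (3.60) and rtTA3 (0.73). It was not called higher in WPRE (0.09, adjusted p = 0.563), PuroR (0.23, 0.747) or 3LTR (-0.65, 0.0681), which lend higher vector transcription no support. The lower RRE (-3.75) cannot weigh here. Its mean log2 CPM in treated 596-7 was -6.33, near the lowest value of those libraries (-6.42), and only treated 596-11 lay above 0 (0.30). A single clone also differs in much else, and vector transcription cannot be told apart from its other differences.

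In 10 of 128 groups of 4 NextSeq values of named genes 1 library lay far from the other 3 (gap to the nearest as a share of the range), where chance gives about 1 in 20, and all 10 were untreated libraries: the first for HERC5 (0.832) and TNC (0.952), the second for AREG (0.946), GADD45A (0.862), RPL7A (0.876) and UQCRH (0.841), the third-numbered one for MMP13 (0.937), MX2 (0.864) and GPI (0.831), and the fourth-numbered one for IFNB1 (0.867). Of 78 genes named with doxycycline on NovaSeq 71 responded differently between clones by the interaction test, against 8248 of all 14347, and were partly chosen by it. Among them were TRIB3 (4.43e-10), SLFN5, ETS1, PPP1R15A, FILIP1L and SPIRE1 (each 4.70e-10) at the lowest adjusted p. By the same test 22 of 30 list levels differed, as did vector features, among them BleoR (9.58e-04), RFP (8.21e-08), RRE (0.0335), rtTA3 (7.18e-04) and WPRE (0.0121).

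For the number of genes called no other grouping did as well. Of 35 splits of the 8 NextSeq libraries 1, the real one, gave as many as 11996 (highest other 0 with limma). That is the smallest share 35 splits can give. The other splits mix treated and untreated libraries and so count the response as spread, which keeps their calls low. Of 100 relabellings within the NovaSeq clones 1, the real one, gave as many as 8438 (highest other 7880). For the number of lists chance is not excluded on NextSeq, where 7 of 35 splits gave as many as the real 17 (highest other 18). On NovaSeq 4 of 100 gave as many as 16 (highest other 16), under the share set beforehand. All 4 leave 596-7 as labelled, however, so among the 29 that do so chance is not excluded for the lists. The 28 other NovaSeq relabellings that leave 596-7 as labelled gave up to 7880 genes and the rest up to 5, so this average rests mostly on 596-7.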

How the results depend on the processing

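Fits with the ribosomal centring, without clone 596-7 and without the first untreated libraries of 596-1 and 596-7 together were tests chosen after the results were seen. No called direction of EFNB2 with doxycycline reversed in any setting, while its average over clones, not called, turned from -0.04 to 0.17 with ribosomal centring (adjusted p = 0.182, not called). For NextSeq 596-7, the average over clones and NovaSeq 596-7 the counts stayed within 1.5 times under the filters, centring on the median, quantile normalization, eBayes variants and leaving out any 1 library. Centring on the median and renewed quantile normalization move almost nothing in tables already quantile normalized and say nothing about stability. A pseudocount on the linear scale was not run, as the values are log2 as deposited, and depth is unknown.

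Requiring an absolute log2 fold change of 1 as well left fewer genes by construction: 6472 on NextSeq, 622 on average, 90 in 596-1, 23 in 596-6, 5478 in 596-7, 180 in 596-11, 4318 on both platforms, and 617, 432, 1009 and 304 in untreated 596-1, 596-6, 596-7 and 596-11. Ribosomal centring gave 167, 97 and 497 calls with doxycycline in 596-1, 596-6 and 596-11, 849 and 729 in untreated 596-6 and 596-11, and EFNB2 falls of -0.91, -0.46 and -0.26 that were no longer called; the cause was not tested. Fits of only the groups compared gave 0 calls in 596-1 (540 at an unadjusted p under 0.05 with limma, EFNB2 -0.86, not called), 2968 in 596-6, 5645 in 596-11 and 1466, 646, 2389 and 390 for the untreated clones in the usual order, since each uses its own spread. Without the first untreated libraries of 596-1 and 596-7 together, 3984, 3048 and 5078 genes were called in 596-1, 596-6 and 596-11, 9644 by the F test of untreated clones, and 5475, 7470 and 5885 in untreated 596-6, 596-7 and 596-11; the cause was not tested. Without 596-7 the average had 2719 genes and 9 lists, EFNB2 was called there (-0.64), the interaction had 39 genes and the untreated F test 2819, where leaving aside any other clone in the same fit gave 8589 to 8852, 8453 to 8662 and 3793 to 5216.

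Among treated libraries the same contrasts gave 11023 genes by the F test, and 7009, 6215, 11216 and 5987 for 596-1, 596-6, 596-7 and 596-11, with 2, 1, 1 and 2 chromosomes. EFNB2 reversed there in 596-1 (-0.49), 596-6 (-0.41) and 596-7 (1.88), as its response to doxycycline implies, and C1QTNF3-AMACR in 596-6 (1.72, not called); for the rest the cause was not tested. With an estimated correlation 3, 4, 1, 2, 4 and 5 lists were called with doxycycline (NextSeq, average, 596-1, 596-6, 596-7, 596-11), 1, 5, 4 and 0 in the untreated clones, and 2, 1, 2 and 1 chromosomes. Fry, which tests lists on their own, called 29 on NextSeq, 25 on average, 27 in 596-7 and 2 in 596-6. The stricter filter left 2 lists in 596-1, and ribosomal centring 5 in 596-6 and 7 in untreated 596-1; the cause was not tested.

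Leaving out 1 library, with the lone one left assumed to vary like other groups, gave 145 to 6533 genes in 596-1, 35 to 721 in 596-6, 237 to 2288 in 596-11; in the untreated clones 3987 to 10324 by the F test and 2713 to 8424, 687 to 4089, 2959 to 7684 and 439 to 4131; EFNB2 ranged from -0.64 to -0.58 in 596-6 and from -0.55 to -0.34 in 596-11, not called at -0.58 in the former and in the latter at -0.34 and without either untreated library (about -0.45, adjusted p = 0.0647 and 0.0726); the cause was not tested.

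A replicate block gave 218 calls and 1 list in 596-1, 55 calls in 596-6 and 382 in 596-11 and moved no other count by over 1.5 times. Same-numbered libraries of a clone correlated in their deviations at -0.11 to 0.02 on NextSeq, where 0 of 4 untreated libraries were closest to their own number, and at -0.07 to 0.19 on NovaSeq. Across clones, the first and second untreated libraries differed alike in 596-1 and 596-7 (r = 0.51, other pairs of clones -0.08 to 0.12), so a batch shared by these 2 first libraries is not ruled out. Of 268 gene values given above 47 lost the call or turned in at least 1 setting.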

Other observations

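In this part the tests without related genes and without interferon genes were set beforehand, while the tests of random placement, of clone-specific pairs and of chromosomes in treated libraries were chosen after the result was seen.

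In the clones with a smaller response, induced genes were often next to each other among the tested genes of a chromosome, which may leave untested genes between them. In 596-11 TERB1 (7.45) and NAE1 (1.90) both rose on chromosome 16, CROT (0.53) and ABCB1 (4.53, and 10.22 in 596-7) on chromosome 7, as did SEMA3A (0.54) and KIAA1324L (3.08), which span 3104 kb there, and IZUMO1 (1.58), FUT1 (0.64) and FGF21 (2.83) on chromosome 19. Pairs of 1 clone were also RAB40C (1.44) and WFIKKN1 (3.96) on chromosome 16 in 596-6 and NCOA4 (0.62) and GPRIN2 (3.69) on chromosome 10 in 596-1. Other pairs rose in all 3 clones, among them C4BPA with CD55 and HSD17B11 with NUDT9. These genes were picked after their values were seen.

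Pairs of neighbouring rises numbered 32 in 596-1, 12 in 596-6 and 42 in 596-11, against means of 7.61 and 0.864 in random sets of the same size for the first 2, and a highest count of 28 for the last. Random placement is argued against, since at most 0.01 percent of 10000 random sets held as many pairs. Related genes that share reads are argued against as the whole account (0.2 percent at most with 1 gene kept per family or overlap). They may cover part, since 596-1, 596-6 and 596-11 then had 16, 8 and 24 pairs against random means of 6.89, 0.775 and 11.8. Runs of genes on the interferon list are argued against as the whole account too (0.06 percent at most without that list). Without it 18, 7 and 25 pairs were left against random means of 6.08, 0.586 and 11.6. With both restrictions 14, 6 and 21 were left (means 6.11, 0.597 and 10.4), so part of the excess went with them in each clone. Interferon-responsive genes outside that list were kept in, so the test cannot decide about them. A candidate explanation is transcription that runs out of vector insertion sites into flanking genes, which the positions of 29 of the 53 pairs, found in 1 of these 3 clones each, would allow, though 8 of the 53 span 500 kb or more. Of the 29, 5 hold a gene of the interferon list. Among the other 24 both genes also rose in 596-7 in 13 and neither in only 3. Of all single genes called up, 403 of 448 in 596-11, 234 of 331 in 596-1 and 87 of 112 in 596-6 also rose in 596-7. With rates that high, the pair counts weigh neither way. Transcription out of insertion sites cannot be told apart from clone-specific regulation, because reads that join vector and genome were not available. The 9 pairs found in all 3 clones would need another account.

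The chromosome differences may come from copy number. If so they should hold at a similar size with and without doxycycline. The median difference of chromosome 12 genes in 596-1 was -0.41 in untreated and -0.31 in treated libraries, against 0.00 and 0.06 for the other genes. For chromosome 11 in 596-7 it was -0.38 and -0.70, against 0.06 and -0.09 for the other genes, so a shift of all genes makes up part of the larger value among treated libraries and copy number alone would leave the rest open. For chromosome 7 in 596-7 it was -0.29 and -0.33, against 0.05 and -0.10, no longer called among treated libraries (adjusted p = 0.554), where most genes of that clone had moved, and copy number cannot be told apart from other causes there. DNA was not measured.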
